A study of Mus musculus with 9 samples.

How the data were processed

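Primary astrocyte cultures from the cerebral cortex of mouse pups were either left untreated or exposed to 200 µM hydrogen peroxide for 3 h and harvested 24 or 72 h after washing, and RNA libraries were made with a poly(A) RNA kit, per the labels' protocols. The labels give 3 libraries for each of 3 groups, and each of the 9 columns of the deposited table was matched to its library by the column name recorded in that library's description. No column was left without a library.

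The deposited table holds FPKM, fragments scaled by gene length and library total, computed by the authors for each library separately; no raw counts were used here. Per the submitters' processing notes, FastQC 0.12.1, cutadapt 2.6, STAR 2.7.3a and DESeq2 were used with the builds GRCm38 and mm10. The counting program, the annotation, the handling of strand and any filter are not given in the sources used here. The table lists 25239 gene symbols without duplicates, of which 4889 are at 0 in every library and 99.2% are in the RefSeq table for GRCm38.p6, from which coordinates were taken.

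The authors' values keep the depth. For all 20350 genes above 0, the deposited FPKM times a whole gene length and a whole library total gave whole reads to within 0.01 read. The recovered reads sum to 99.91% to 99.94% of the library totals, which run from 23032594 to 38414668. For a gene of 2 kb, 1 FPKM stands for 46.1 to 76.8 reads. Replicates of a group differed by more than sampling noise: the chi-square per degree of freedom of their recovered reads, over genes with at least 20 reads in a pair and without Rn45s, was 1.84 to 5.45. Because the labels do not say whether replicates are separate cultures, the spread between them may be technical.

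Counts were planned for the main test, with edgeR's quasi-likelihood fit, and the deposited unit turned out to be FPKM, so edgeR was not used here. The FPKM were rescaled with median-of-ratios factors of 0.976 to 1.02, since the 45S ribosomal RNA precursor Rn45s took 7.67% to 11.9% of reads. This scaling was chosen after the share was seen and before any test was run. Genes with a mean of at least 1 FPKM over the 9 libraries were kept (12611), values were taken as log2(FPKM + 0.1), and all libraries were fitted together with group as the only term by limma 3.58.1 in R 4.3.3, with an intensity trend for the variance. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The labels give no covariate and no shared culture day, and the replicate number was tried as an alternative.

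The 28 gene lists (510 genes, all found in the table) and the comparisons were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way and not whether they differ from other genes, was run beside it. Marker lists overlap what cultured astrocytes themselves express, so a marker is not exclusive to its cell type here. The rule for naming genes, fixed at the same time, took the 6 largest rises and falls against control (4 between the days) among called genes whose groups do not overlap and whose higher group has at least 5 CPM. It added up to 2 risen and 2 fallen members of each list with a camera adjusted p under 0.05 and of both collagen lists, and 8 genes whatever their values: Col1a1, Col1a2, Col3a1, Gfap, Cdkn1a, Hmox1, Nqo1 and Cat. Some genes that the rule names are not reported here. Dcn is given on day 1 as well, a comparison in which the rule does not name it, chosen after its values were seen.

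The fit was tested on simulated data: reads were drawn for the 12611 genes with the real library sizes, and 200 genes were changed on day 1. For day 1 against control all 50 genes changed by 0.5 on the log2 scale were recovered, as were all 50 changed by 1, while 33 of 50 changed by 0.25 were, with 11 of 12411 unchanged genes called. For day 3 against control, where nothing was changed, 0 of 12611 genes were called. The simulation gave all genes the same dispersion (0.000444) and changed few of them, whereas 62.2% of genes were called on day 1 in the real data. It therefore does not give the error rate of the real comparison. Alternatives covered the pseudocount, the filter, the libraries in the fit, the replicate block, stricter thresholds, no rescaling, each library left out in turn, and some chosen after the data were seen. The planned edgeR and DESeq2 alternatives were not run, since the deposited values used here are FPKM; the reads recovered from the FPKM were tested with limma-voom. Figures were drawn with matplotlib 3.10.9.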

Results

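The series measured polyadenylated RNA by sequencing in primary mouse cortical astrocytes, a glial culture grown from the cerebral cortex of pups at postnatal day 4. Cultures were exposed to 200 µM hydrogen peroxide for 3 h, washed, and harvested 24 h (day 1) or 72 h (day 3) later. There were 3 untreated control libraries, 3 day 1 libraries and 3 day 3 libraries. The series title names astrocytic collagen induced by hydrogen peroxide, so the collagen genes were the first items examined. The control libraries held 30278210, 38414668 and 31500443 reads, the day 1 libraries 23658076, 27850348 and 23032594, and the day 3 libraries 30545004, 36633113 and 36749577, as worked out from the FPKM. The labels give no harvest time for the controls and do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are FPKM as deposited, given as mean ± SD with n = 3, and fold changes are on the log2(FPKM + 0.1) scale after rescaling between libraries, which understates changes of low genes.

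On day 1 the main fibrillar collagens, which form the load-bearing fibres of connective tissue, were higher than in control. Col1a1 (chromosome 11, 94936224 to 94953042, GRCm38.p6) rose from 392 ± 20.3 to 1026 ± 49.8 FPKM, a 2.67-fold change with a 95% interval of 2.38 to 3.00 (limma adjusted p = 1.08e-07). Col1a2 (chromosome 6, 4505618 to 4541543) rose from 308 ± 12.2 to 723 ± 27.0 FPKM, and Col3a1 (chromosome 1, 45311538 to 45349706) from 177 ± 5.17 to 282 ± 1.10 FPKM. Col5a1 rose 2.69-fold, from 49.3 ± 2.15 to 130 ± 4.47 FPKM. Of 10 fibrillar collagens tested, 6 rose, 1 fell and 3 did not pass, and the counts were the same when adjusted over the list alone. The member that fell was Col11a2, a collagen best known from cartilage, which went from 9.12 ± 0.452 to 4.49 ± 0.454 FPKM. The list stood above other genes by camera (adjusted p = 0.00987), but not with an estimated correlation (adjusted p = 0.254).

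The other collagens went both ways on day 1: of 21 tested, 10 rose and 10 fell, also when adjusted over the list alone. Col6a3 rose 4.10-fold, from 9.62 ± 0.327 to 38.9 ± 0.853 FPKM, and Col7a1, which forms anchoring fibrils, rose 3.74-fold. Col20a1 fell 3.71-fold and Col8a2 fell 3.13-fold, both from under 10 FPKM. The list as a whole did not differ from other genes (camera adjusted p = 0.644). Its median log2 fold change was -0.03 and its mean -0.06, while camera and fry both gave an upward direction.

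Genes that modify and cross-link collagen rose with the fibrillar collagens on day 1. Of 25 tested, 22 rose and 2 fell, and the counts were the same adjusted over the list alone (camera adjusted p = 3.53e-07; adjusted p = 0.254 with an estimated correlation). The cross-linking enzyme Lox rose 2.83-fold, from 76.4 ± 2.48 to 212 ± 13.0 FPKM, and Loxl2 rose 2.51-fold. P4ha3, a subunit of prolyl 4-hydroxylase, fell 1.31-fold and P3h2 fell 1.13-fold. Of 28 other matrix proteins, 18 rose and 8 fell, again unchanged when adjusted over the list alone (camera adjusted p = 0.00533; adjusted p = 0.255 with an estimated correlation). Fbln2 rose 4.09-fold and Tnc, which encodes tenascin C, rose 3.61-fold from 44.3 ± 1.53 to 157 ± 3.43 FPKM. Vtn fell 4.33-fold and Tnr, a component of the nets around neurons, fell 1.72-fold. Matrix proteases and their inhibitors went both ways, with 9 higher and 6 lower of 17 (camera adjusted p = 0.427).

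**Figure D1:**
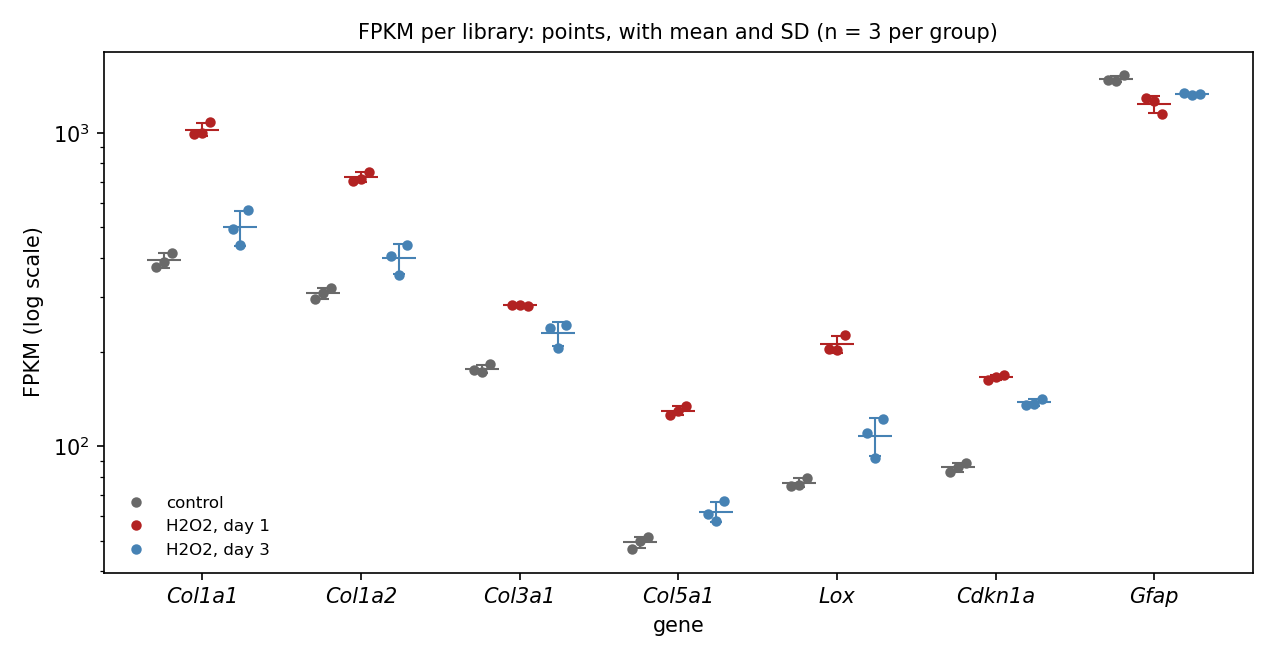
FPKM as deposited (log axis) of 7 genes in each library, with points for the 3 libraries of each group and a bar with whiskers for mean ± SD. Col1a1 averaged 392 FPKM in control, 1026 on day 1 and 501 on day 3, while Gfap averaged 1493, 1235 and 1333 FPKM.

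Genes of the TGF-beta pathway and its known targets were also higher on day 1, with 16 higher and 2 lower of 22, the same adjusted over the list alone (camera adjusted p = 3.23e-05; adjusted p = 0.246 with an estimated correlation). Inhba, a subunit of activin, rose 6.16-fold from 2.57 ± 0.101 to 16.1 ± 1.86 FPKM. The co-receptor gene Tgfbr3 fell 2.51-fold and Ltbp3 fell 1.15-fold. Markers of mural and smooth muscle cells moved the same way, with 5 of 6 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.000787; adjusted p = 0.254 with an estimated correlation). Acta2, smooth muscle actin, rose from 479 ± 15.2 to 996 ± 29.5 FPKM and Actg2 rose 3.44-fold. Acta2 and Actg2 share much coding sequence, and how reads that match both were counted is not given in the sources used here.

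The 6 largest rises on day 1, among called genes whose groups did not overlap and with at least 5 CPM in the higher group, included low genes. Has2, a hyaluronan synthase, rose 10.6-fold from 0.400 ± 0.0212 to 5.09 ± 0.482 FPKM. Anxa8 rose 7.43-fold. By the same criteria the largest falls included Gpr17 (12.9-fold), Apod (11.4-fold), Bcas1 (7.74-fold) and Cldn11 (5.43-fold). C3, the central complement component, fell 6.57-fold from 87.8 ± 7.66 to 13.0 ± 1.66 FPKM, and Ptgds fell 5.48-fold.

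Genes of the astrocyte lists also shifted on day 1, in bulk RNA that does not show which cells changed. Of 19 homeostatic astrocyte genes, 15 fell and 2 rose, with 15 and 3 when adjusted over the list alone (camera adjusted p = 5.55e-06; adjusted p = 0.281 with an estimated correlation). Apoe fell 2.22-fold from 2997 ± 119 to 1320 ± 84.8 FPKM and Ntsr2 fell 2.19-fold, while Aldh1l1 rose 1.26-fold and Aqp4, the water channel, rose 1.12-fold. Gfap, the intermediate filament of astrocytes, went from 1493 ± 33.7 to 1235 ± 76.8 FPKM (adjusted p = 0.000313). Quantile normalization, a scaling chosen after seeing the data, ended the calls for Gfap (log2 fold change -0.03, adjusted p = 0.419) and Aqp4 (0.05, adjusted p = 0.222). Genes of the A2 reactive list were higher in 7 and lower in 2 of 11, the same adjusted over the list alone (camera adjusted p = 0.0308; adjusted p = 0.254 with an estimated correlation). Among them Ptgs2, the inducible cyclooxygenase, rose 4.72-fold and Ptx3 rose 1.91-fold, while Cd14 fell 1.51-fold. The A1 reactive list (1 higher, 6 lower of 10, camera adjusted p = 0.0732) and the pan-reactive list (5 higher, 8 lower of 13, camera adjusted p = 0.252) did not pass.

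Several stress and metabolic groups were higher on day 1. Targets of p53 rose in 19 of 22 and fell in 1, the same adjusted over the list alone (camera adjusted p = 4.76e-08; adjusted p = 0.246 with an estimated correlation). The 1 that fell, Sesn1, passed in no fit without 1 library except that without day 1 replicate 1: adjusted p was 0.118, 0.0906 and 0.0624 without control replicate 1, 2 and 3, 0.0511 and 0.154 without day 1 replicate 2 and 3, and 0.0562, 0.0571 and 0.0600 without day 3 replicate 1, 2 and 3. It did not pass with only the 6 libraries compared either (0.0705). Pmaip1, a pro-apoptotic gene, rose 4.02-fold, Ccng1 rose 2.28-fold, and the cell cycle inhibitor Cdkn1a rose 1.98-fold from 85.6 ± 2.69 to 166 ± 3.10 FPKM. Genes of the unfolded protein and integrated stress responses rose in 11 and fell in 2 of 15 (camera adjusted p = 0.000819; adjusted p = 0.246 with an estimated correlation), led by Trib3 (3.76-fold) and Asns (2.67-fold). Of the 2 that fell, Sdf2l1, did not pass without control replicate 3 (adjusted p = 0.0792) or day 1 replicate 1 or 2 (0.0811 and 0.0909). Cholesterol synthesis genes rose in 16 and fell in 1 of 19 (camera adjusted p = 1.03e-05; adjusted p = 0.246 with an estimated correlation), among them Idi1 (1.58-fold) and Msmo1 (1.53-fold). Counts for both lists were the same adjusted over the list alone. The list of targets of NRF2, the main antioxidant transcription factor, did not pass (11 higher, 5 lower of 20, camera adjusted p = 0.0706). It passed without control replicate 2 (adjusted p = 0.0433), as did the cell cycle list (13 higher, 6 lower of 29, adjusted p = 0.144 with that library and 0.0218 without it). Of the antioxidant genes named in advance, Nqo1 rose 2.06-fold (adjusted p = 3.02e-07). Cat, which encodes catalase, was 1.08-fold higher (adjusted p = 0.00224), a call that quantile normalization ended (adjusted p = 0.161). Hmox1 was at 99.6 ± 6.60 FPKM in control and 102 ± 8.41 on day 1 (adjusted p = 0.416).

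Markers of other cell types also moved on day 1. Microglia markers fell in 16 and rose in 1 of 17 (camera adjusted p = 3.53e-07; adjusted p = 0.254 with an estimated correlation). The complement gene C1qa fell from 60.5 ± 4.89 to 19.1 ± 1.13 FPKM and Ly86 fell 3.15-fold, while Tmem119 rose 1.72-fold. Markers of the oligodendrocyte lineage fell in 11 and rose in 1 of 12 (camera adjusted p = 3.03e-06; adjusted p = 0.246 with an estimated correlation). Gpr17 fell from 11.8 ± 0.998 to 0.802 ± 0.0769 FPKM, whereas Cspg4, which mural cells also express, rose 2.35-fold. All 5 ependymal markers tested fell (camera adjusted p = 0.00987; adjusted p = 0.254 with an estimated correlation), including Rarres2 (2.06-fold) and Ccdc153 (1.90-fold). Fibroblast markers, which bear on the source of collagen RNA, rose in 8 and fell in 5 of 14 (camera adjusted p = 0.417). Dcn, which encodes the proteoglycan decorin, fell 4.90-fold from 45.1 ± 1.85 FPKM in control to a mean of 9.01 FPKM. Counts for these 4 lists were the same adjusted over the list alone.

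The remaining lists did not pass on day 1. They were peroxide and superoxide removal (7 higher, 3 lower of 15, camera adjusted p = 0.184), heat shock proteins and metallothioneins (7 and 3 of 13, 0.223), interferon response (0 and 5 of 9, 0.121) and NF-kappaB cytokines and adhesion (3 and 3 of 9, 0.644). Glycolysis and hypoxia (10 and 7 of 21, 0.644), putrescine, GABA and urea metabolism (3 and 4 of 10, 0.979), neuron markers (3 and 2 of 5, 0.867) and endothelial markers (1 and 1 of 3, 0.666) did not pass either. Adjusted over the list alone, glycolysis and hypoxia had 10 genes higher and 8 lower, and the other lists of this paragraph kept their counts. For the neuron list the median was 0.10 and the mean -0.10, with camera upward and fry downward. For glycolysis the median was 0.03 and the mean -0.01, and for putrescine they were -0.01 and -0.03, while camera and fry were upward for both.

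Across all 12611 genes tested, 3923 were higher and 3916 lower on day 1 than in control (limma, Benjamini-Hochberg adjusted p under 0.05), or 62.2%. Of these, 186 higher and 247 lower genes changed at least 2-fold. The 3 values of one group lay apart from those of the other for 67.2% of genes, where chance gives 10%. The first principal component, with 64.1% of the variance, set the day 1 libraries apart from the other 6. The share of reads on Rn45s, the 45S ribosomal RNA precursor, moved with this comparison: it was 11.9%, 9.41% and 9.60% in the control libraries and 8.10%, 7.67% and 9.36% in the day 1 libraries, with no overlap. Without the 2 libraries with the highest share, control replicate 1 and day 3 replicate 2, 3616 genes were higher and 3625 lower. The balance of directions depended on the scaling, with 3319 higher and 4348 lower from FPKM as deposited.

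On day 3, 6 of 10 fibrillar collagens were higher than in control and 3 were lower, the same adjusted over the list alone. Col1a1 was at 501 ± 64.9 FPKM, 1.28-fold above control with a 95% interval of 1.14 to 1.44 (adjusted p = 0.0105). Col1a2 was at 399 ± 43.1 FPKM and Col3a1 at 229 ± 20.7 FPKM, 1.30-fold and 1.31-fold above control. Col11a1 fell from 51.1 ± 1.35 to 33.4 ± 1.44 FPKM and Col11a2 fell 2.46-fold. The list did not differ from other genes (camera adjusted p = 0.22); its median log2 fold change was 0.21, its mean -0.02, camera gave an upward and fry a downward direction. Of 21 other collagens, 10 rose and 8 fell, or 11 and 10 adjusted over the list alone (camera adjusted p = 0.583). Col6a3 (1.47-fold) and Col7a1 (1.43-fold) rose, and Col20a1 (2.86-fold) and Col9a1 (2.04-fold) fell. Their median was 0.10 and their mean -0.13, with camera upward and fry downward.

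Other matrix groups were higher on day 3. Collagen processing genes rose in 10 of 25 with none lower, or 13 adjusted over the list alone (camera adjusted p = 3.50e-05; adjusted p = 0.251 with an estimated correlation), with Lox 1.42-fold and Loxl2 1.30-fold higher. Other matrix proteins rose in 12 and fell in 2 of 28, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.000307; adjusted p = 0.155 with an estimated correlation). Fbln2 (1.55-fold) and Thbs2 (1.53-fold) rose, and the proteoglycan Bcan (1.31-fold) and Tnr (1.51-fold) fell. Matrix proteases and inhibitors rose in 8 and fell in 2 of 17, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00187; adjusted p = 0.107 with an estimated correlation), with Timp1 1.52-fold and Mmp2 1.41-fold higher and Mmp15 1.22-fold lower. TGF-beta genes rose in 11 and fell in 1 of 22, or 14 and 1 adjusted over the list alone (camera adjusted p = 4.47e-06; adjusted p = 0.108 with an estimated correlation), with Inhba 1.41-fold higher. The fallen member was Tgfb2 (1.13-fold), which did not pass without control replicate 2 (adjusted p = 0.0559). Fibroblast markers rose in 9 of 14 and none fell, or 12 adjusted over the list alone (camera adjusted p = 7.43e-07; adjusted p = 0.0612 with an estimated correlation). Among them Lum rose 1.52-fold, from 3.36 ± 0.339 to 5.07 ± 0.121 FPKM. The 10 collagen processing genes higher were 5, 4 and 6 without control replicate 1, 2 and 3, and 5 and 4 without day 3 replicate 1 and 3. The 8 proteases and inhibitors higher were 5 without control replicate 1 or 2 or day 3 replicate 1 or 3. Of the 2 that fell, Mmp16, did not pass without control replicate 1, 2 or 3 (adjusted p = 0.148, 0.0774 and 0.0745), day 1 replicate 1 (0.0561) or day 3 replicate 1, 2 or 3 (0.0959, 0.109 and 0.105), nor with the replicate number as a block (0.0531). The 9 fibroblast markers higher were 5 without control replicate 2 or day 3 replicate 3. Mural and smooth muscle markers did not pass (1 higher, 2 lower of 6, or 2 and 2 adjusted over the list alone, camera adjusted p = 0.631), with a median of 0.05, a mean of -0.0029 and a downward direction in camera and fry. Without day 3 replicate 2 the mural markers higher were 2.

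Targets of p53 were higher on day 3 as well. Of 22, 19 were higher and none lower, or 20 adjusted over the list alone (camera adjusted p = 3.00e-20). It was the one list of 28 that also passed with an estimated correlation (adjusted p = 0.0447). Cdkn1a was at 138 ± 3.21 FPKM, 1.63-fold above control (adjusted p = 9.34e-07), and Pmaip1 was 1.65-fold higher. Cell cycle genes moved the other way: 26 of 29 were lower and none higher, or 27 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.13e-21; adjusted p = 0.0976 with an estimated correlation). The kinetochore gene Cenpf fell 1.63-fold, from 2.73 ± 0.276 to 1.61 ± 0.101 FPKM, and the mitotic kinase gene Aurkb fell 1.48-fold.

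Markers of the oligodendrocyte lineage were also lower on day 3, with 9 of 12 lower and none higher, or 10 adjusted over the list alone (camera adjusted p = 1.38e-12; adjusted p = 0.0612 with an estimated correlation). Gpr17 was at 2.67 ± 0.118 FPKM and Bcas1 at 3.15 ± 0.232 FPKM, against 11.8 ± 0.998 and 13.5 ± 0.146 in control. Sox10, a transcription factor of this lineage, fell 2.58-fold. Slc1a1, a glutamate transporter gene, and the connexin gene Gjc3 also fell (2.88-fold and 2.58-fold). Microglia markers, all 17 of them, did not pass a test in either direction (camera adjusted p = 0.334), and C1qa stood at 54.4 ± 8.25 FPKM. Ependymal markers likewise had none of 5 past the threshold (camera adjusted p = 0.285). Without day 3 replicate 2, 1 of them was lower.

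**Figure D2:**
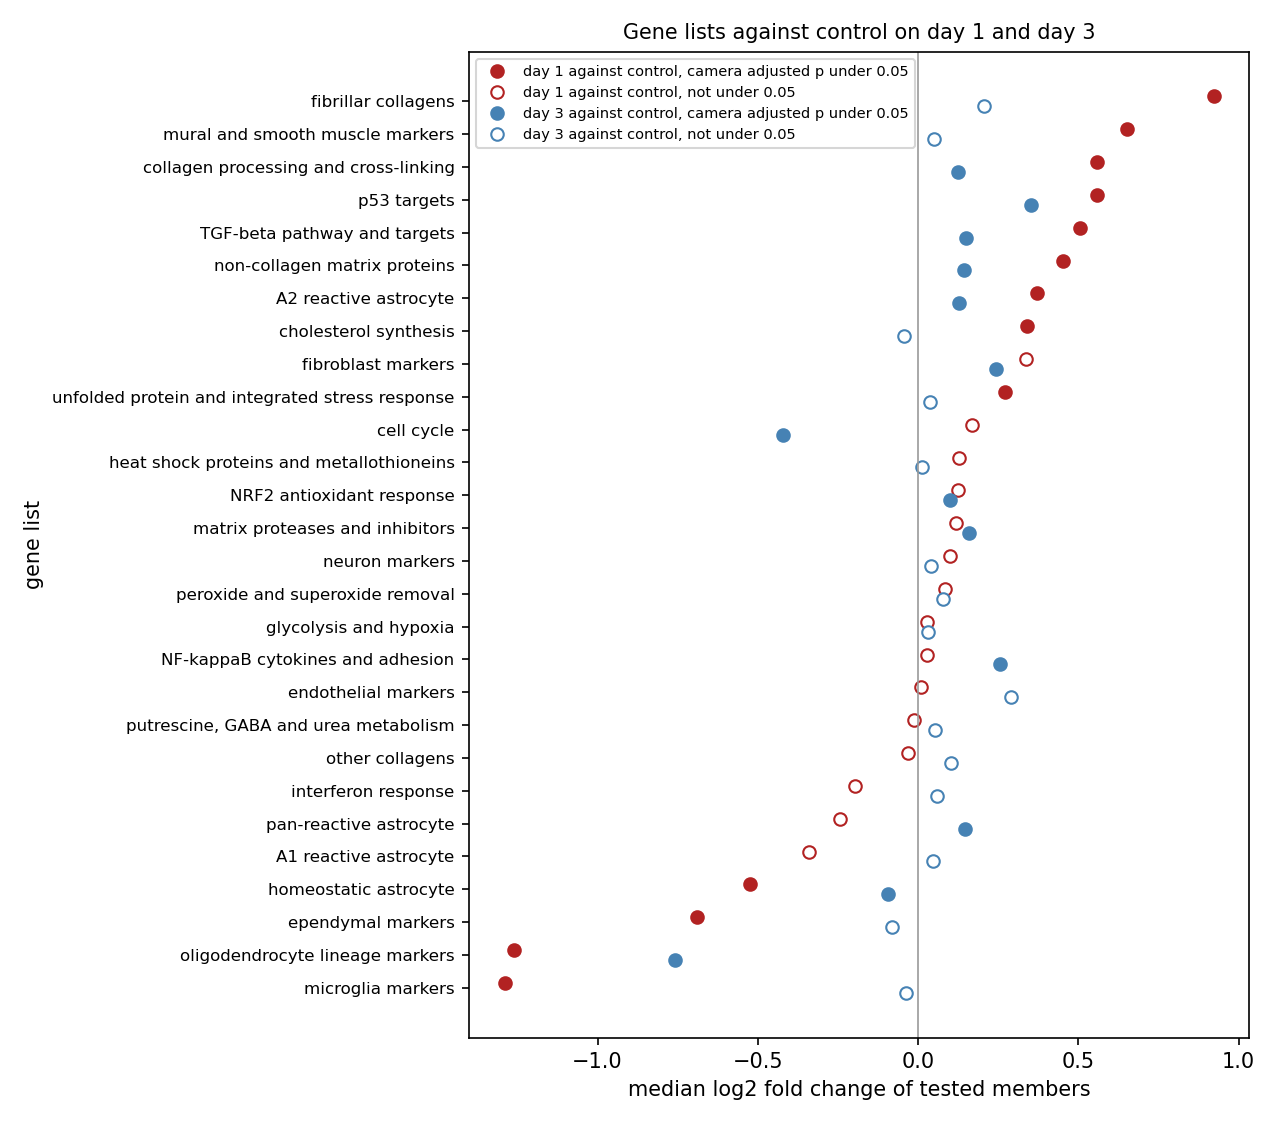
Median log2 fold change of the tested members of each of the 28 gene lists (horizontal axis) against control on day 1 (red) and day 3 (blue); filled points have a camera adjusted p under 0.05. Fibrillar collagens had a median of 0.92 on day 1 and 0.21 on day 3, and cell cycle genes 0.17 and -0.42.

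Several astrocyte and stress groups also passed on day 3. Homeostatic genes fell in 8 of 19 and none rose (camera adjusted p = 0.001; adjusted p = 0.422 with an estimated correlation), with S100b 1.24-fold and Sparcl1 1.19-fold lower. NRF2 targets rose in 9 of 20 with none lower (camera adjusted p = 1.11e-05; adjusted p = 0.0934 with an estimated correlation), among them the cystine transporter Slc7a11 (1.37-fold) and G6pdx (1.25-fold). The A2 list rose in 5 of 11 with none lower (camera adjusted p = 0.000447; adjusted p = 0.1 with an estimated correlation), led by Ptgs2 (1.58-fold) and Cd109 (1.30-fold). The pan-reactive list rose in 7 and fell in 2 of 13 (camera adjusted p = 0.0242; adjusted p = 0.113 with an estimated correlation), and NF-kappaB genes rose in 4 of 9 with none lower (camera adjusted p = 0.00195; adjusted p = 0.132 with an estimated correlation). Il33 was 1.30-fold higher. Ccl2, with the largest rise of the 4, went from 2.08 ± 0.295 to 2.83 ± 0.246 FPKM (limma adjusted p = 0.0282). It did not pass without control replicate 1 or 3 (adjusted p = 0.0953 and 0.0808) or day 3 replicate 1, 2 or 3 (0.0559, 0.0835 and 0.0583). Adjusted over the list alone, these 5 lists gave the same counts. The 8 homeostatic genes lower were 3, 4 and 5 without control replicate 1, 2 and 3, and 3 and 4 without day 3 replicate 1 and 3. Without day 3 replicate 1 the NRF2 targets higher were 5 and the pan-reactive genes higher 4, and both pan-reactive genes that fell, Gfap and Serpina3n, no longer passed (adjusted p = 0.0969 and 0.0508). Only Serpina3n of these 2 passed without control replicate 1, 2 or 3 or day 3 replicate 3. The A2 genes higher were 3 without control replicate 2 and 2 without day 3 replicate 3.

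Of the genes fixed in advance, 3 gave weak calls on day 3. Gfap, a member of the pan-reactive list, was at 1333 ± 8.47 FPKM (adjusted p = 0.0327). It no longer passed without control replicate 1, 2 or 3 (adjusted p = 0.0876, 0.0516 and 0.113) or day 3 replicate 1 or 3 (0.0969 and 0.103), nor with log2(FPKM + 1) and no filter on low values together (0.168). Hmox1 was at 115 ± 3.69 FPKM, 1.17-fold above control (adjusted p = 0.0309), and no longer passed without control replicate 1 or 3 (0.103 and 0.0684) or without day 3 replicate 1, 2 or 3 (0.0734, 0.0504 and 0.102), nor with log2(FPKM + 1) and no filter (0.0782). Cat was 1.08-fold higher (adjusted p = 0.0131), and not past the threshold without day 3 replicate 1 or 3 (0.0535 and 0.0519) or with FPKM as deposited (0.075). Nqo1 was at 6.43 ± 0.352 FPKM against 6.05 ± 0.505 in control (adjusted p = 0.35).

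The lists that did not pass on day 3 were A1 reactive genes (2 higher, 0 lower of 10, camera adjusted p = 0.204), peroxide and superoxide removal (3 and 0 of 15, 0.125), and heat shock proteins and metallothioneins (1 and 0 of 13, 0.327). Interferon response (0 and 0 of 9, 0.309), cholesterol synthesis (3 and 2 of 19, 0.24), glycolysis and hypoxia (0 and 2 of 21, 0.583), putrescine, GABA and urea metabolism (2 and 0 of 10, 0.176) and neuron markers (2 and 1 of 5, 0.868) did not pass. Adjusted over the list alone, the counts were 6 and 2 for peroxide removal, 3 and 4 for cholesterol synthesis, 3 and 0 for putrescine metabolism and 2 and 2 for neuron markers, and 5 and 0 for the unfolded protein response; the others of this paragraph kept theirs. For neuron markers the median was 0.04 and the mean -0.08, with camera upward and fry downward. Leaving out 1 library moved these small counts. A1 genes higher were 1 without control replicate 2, day 1 replicate 1 or 2 or day 3 replicate 1 or 2. Peroxide removal genes higher were 1 without day 3 replicate 3, and lower 1 without control replicate 1, day 1 replicate 3 or day 3 replicate 2. Cholesterol genes higher were 1 without control replicate 2 or 3 or day 3 replicate 3, and lower 0 without control replicate 1 or day 3 replicate 1 and 1 without control replicate 3 or day 3 replicate 2. Glycolysis genes lower were 0 without control replicate 1 and 1 without day 3 replicate 1 or 3, and higher 1 without day 1 replicate 3. Neuron markers higher were 1 without control replicate 1 or 2, day 1 replicate 3 or day 3 replicate 2 or 3, and lower 2 without day 3 replicate 2. The unfolded protein list (3 and 0 of 15) and the endothelial list (2 and 0 of 3) both stood at 0.0697. Unfolded protein response genes higher were 1 without control replicate 1 or 3 or day 3 replicate 3 and 0 without day 3 replicate 1. Both passed without day 3 replicate 1 (0.0499), and the endothelial list also with FPKM as deposited (0.0335).

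Over all 12611 genes, 929 were higher and 813 lower on day 3 than in control (limma adjusted p under 0.05), or 13.8%, of which 4 and 21 changed at least 2-fold. The largest rises among called genes whose groups did not overlap and with at least 5 CPM in the higher group were in Wnt2, a secreted signalling protein (2.01-fold, from 1.16 ± 0.154 to 2.39 ± 0.164 FPKM), Svop (1.97-fold) and Medag (1.68-fold). Vnn1 (1.66-fold) and Lrrc32 (1.63-fold) were next apart from Pmaip1. These counts dropped when any 1 library of the groups compared was left out, except day 3 replicate 2. There were 569 higher and 464 lower without day 3 replicate 1, and 534 and 491 without day 3 replicate 3. Without control replicate 1, 2 and 3 they were 631 and 553, 654 and 544, and 653 and 535. Without day 3 replicate 2 they stayed at 921 higher and 809 lower. Between day 3 replicates 1 and 3 the chi-square per degree of freedom of recovered reads was 2.5. In the pairs of replicate 2 with replicates 1 and 3 it was 4.22 and 5.45. The groups did not overlap for 32.6% of genes, where chance gives 10%. From FPKM as deposited, 661 were higher and 861 lower.

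The direct comparison of day 3 with day 1 tested the difference between the times. Fibrillar collagens were lower on day 3 in 8 of 10 and higher in none, the same adjusted over the list alone (camera adjusted p = 4.30e-05; adjusted p = 0.19 with an estimated correlation). Col1a1 was 2.08-fold lower (adjusted p = 1.26e-06), Col1a2 1.84-fold, Col3a1 1.25-fold and Col5a1 2.13-fold. Of 21 other collagens 8 were higher and 12 lower (camera adjusted p = 0.183), with Col6a3 2.79-fold and Col7a1 2.62-fold lower and Col23a1 2.28-fold and Col8a2 2.16-fold higher. Collagen processing genes were lower in 21 and higher in 2 of 25 (camera adjusted p = 1.54e-06; adjusted p = 0.208 with an estimated correlation), and Lox was 1.99-fold lower. Other matrix proteins (9 higher, 17 lower of 28, camera adjusted p = 0.0236; adjusted p = 0.301 with an estimated correlation) and TGF-beta genes (3 higher, 13 lower of 22, camera adjusted p = 0.000506; adjusted p = 0.208 with an estimated correlation) went the same way. Tnc was 2.94-fold lower, Fbln2 2.63-fold and Inhba 4.38-fold, while Tgfbr3 was 3.06-fold higher. Mural and smooth muscle markers were lower in 5 of 6 and higher in none (camera adjusted p = 0.000506; adjusted p = 0.208 with an estimated correlation), with Acta2 2.49-fold lower.

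Other groups were higher on day 3 than on day 1. Microglia markers were higher in 16 and lower in 1 of 17 (camera adjusted p = 7.59e-08; adjusted p = 0.208 with an estimated correlation), C1qb by 2.84-fold. Homeostatic astrocyte genes were higher in 15 and lower in 2 of 19 (camera adjusted p = 3.38e-06; adjusted p = 0.268 with an estimated correlation), with Apoe 2.04-fold and Ntsr2 1.85-fold higher. Oligodendrocyte lineage markers were higher in 10 and lower in 1 of 12 (camera adjusted p = 0.000294; adjusted p = 0.208 with an estimated correlation), among them Cldn11 (3.32-fold) and Gpr17 (3.04-fold). Ependymal markers (5 of 5 higher, camera adjusted p = 0.00789), interferon genes (5 higher, 0 lower of 9, 0.0153) and A1 reactive genes (7 higher, 1 lower of 10, 0.00404) were higher too, with adjusted p = 0.208, 0.208 and 0.19 with an estimated correlation. The A1 gene Serping1, a complement inhibitor, was 3.02-fold higher. The A1 gene that was lower, H2-T23, did not pass without day 1 replicate 1 or 2 (adjusted p = 0.116 and 0.0797) or day 3 replicate 3 (0.145). The largest rises, among called genes whose groups did not overlap and with at least 5 CPM in the higher group, were Apod (10.2-fold), Dcn (5.76-fold), C3 (5.58-fold) and Lcn2 (4.98-fold), and the largest falls included Has2 (9.43-fold).

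Cell cycle genes were lower on day 3 than on day 1 in 24 of 29, with none higher (camera adjusted p = 5.35e-08; adjusted p = 0.208 with an estimated correlation), Cenpf by 1.94-fold and Ccnb1 by 1.92-fold. Targets of p53 were lower in 15 of 22 with none higher (camera adjusted p = 0.000506; adjusted p = 0.208 with an estimated correlation), with Pmaip1 2.44-fold, Ccng1 1.53-fold and Cdkn1a 1.22-fold lower; 1 was higher without control replicate 1 or 3, day 1 replicate 2 or day 3 replicate 1. Cholesterol synthesis genes (1 higher, 18 lower of 19, camera adjusted p = 2.05e-07) and unfolded protein response genes (2 higher, 11 lower of 15, 0.000653) were lower, both with adjusted p = 0.19 with an estimated correlation. Insig1 was 1.49-fold and Trib3 3.25-fold lower. Of the 2 unfolded protein response genes that were higher, Sdf2l1 did not pass without control replicate 1 or 2 (adjusted p = 0.0513 and 0.0563), day 1 replicate 1 or 2 (0.137 and 0.156) or day 3 replicate 2 or 3 (0.164 and 0.0519), and Pdia4 not without day 1 replicate 2 or 3 (0.0568 and 0.0721) or day 3 replicate 1 (0.0692). Nqo1 was 1.92-fold lower (adjusted p = 1.09e-06) and Hmox1 1.12-fold higher (adjusted p = 0.0344, not under 0.05 without day 1 replicate 1 or 2 or any single day 3 library, 0.0546 to 0.14). Cat was 1.00-fold of day 1 (adjusted p = 0.999) and Gfap 1.07-fold (adjusted p = 0.0584), the latter turning to a fall under quantile normalization (log2 fold change -0.10, adjusted p = 0.0262) and the rise passing without day 1 replicate 1 (0.0289) and with limma-voom on recovered reads (0.00621).

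Adjusted over the list alone, the p53 list had 1 gene higher and 15 lower on day 3 than on day 1, the A1 list 8 and 1, the other matrix proteins 10 and 17, the pan-reactive list 8 and 5 and glycolysis 8 and 8; the other lists kept their counts. The remaining lists did not pass: matrix proteases (7 higher, 8 lower of 17, camera adjusted p = 0.792), pan-reactive (7 and 5 of 13, 0.124), A2 (2 and 7 of 11, 0.0874), NRF2 targets (6 and 10 of 20, 0.626) and peroxide removal (3 and 7 of 15, 0.333). The same held for heat shock proteins (3 and 7 of 13, 0.333), NF-kappaB genes (5 and 3 of 9, 0.629), glycolysis (7 and 8 of 21, 0.792), putrescine metabolism (4 and 4 of 10, 0.792), neuron (1 and 1 of 5, 0.862), fibroblast (6 and 6 of 14, 0.792) and endothelial markers (2 and 1 of 3, 0.792). Neuron markers lower were 2 without day 1 replicate 2 and 0 without day 1 replicate 3, and endothelial markers higher 1 without control replicate 3, day 1 replicate 2 or 3 or day 3 replicate 2 or 3. Median and mean differed in sign for NRF2 targets (-0.07 and 0.02), NF-kappaB genes (0.28 and -0.03), glycolysis (-0.01 and 0.02), neuron (-0.06 and 0.01), fibroblast (-0.02 and 0.19) and endothelial markers (0.28 and -0.25). Camera followed the median in these lists except the fibroblast list, and fry followed the mean for NF-kappaB, neuron, fibroblast and endothelial genes. Over all genes, 3515 were higher and 3577 lower on day 3 than on day 1, or 56.2%, of which 184 and 106 changed at least 2-fold.

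The comparisons with control shared many calls. There were 719 genes higher and 575 lower at both times, against 289 and 252 for independent lists of these sizes. With 3 controls the sharing cannot be removed by splitting them, so part of the excess may come from the shared controls. Fold changes of the 12611 genes on day 1 and day 3 had a covariance of 0.0378, against a mean of 0.00738 in 50 simulations of unchanged groups sharing the controls, a difference of 0.0305. Their correlation was 0.494 across genes, which are not independent replicates, and 0.510 in the simulations. Of 433 genes that changed at least 2-fold on day 1, 183 were called on the same side of control on day 3. There were 287 genes called on day 3 and not on day 1. The 1294 genes called the same way at both times were 778 without day 3 replicate 1 and 765 without day 3 replicate 3. They were 888, 927 and 904 without control replicate 1, 2 and 3, but 1358 without day 3 replicate 2.

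**Figure D3:**
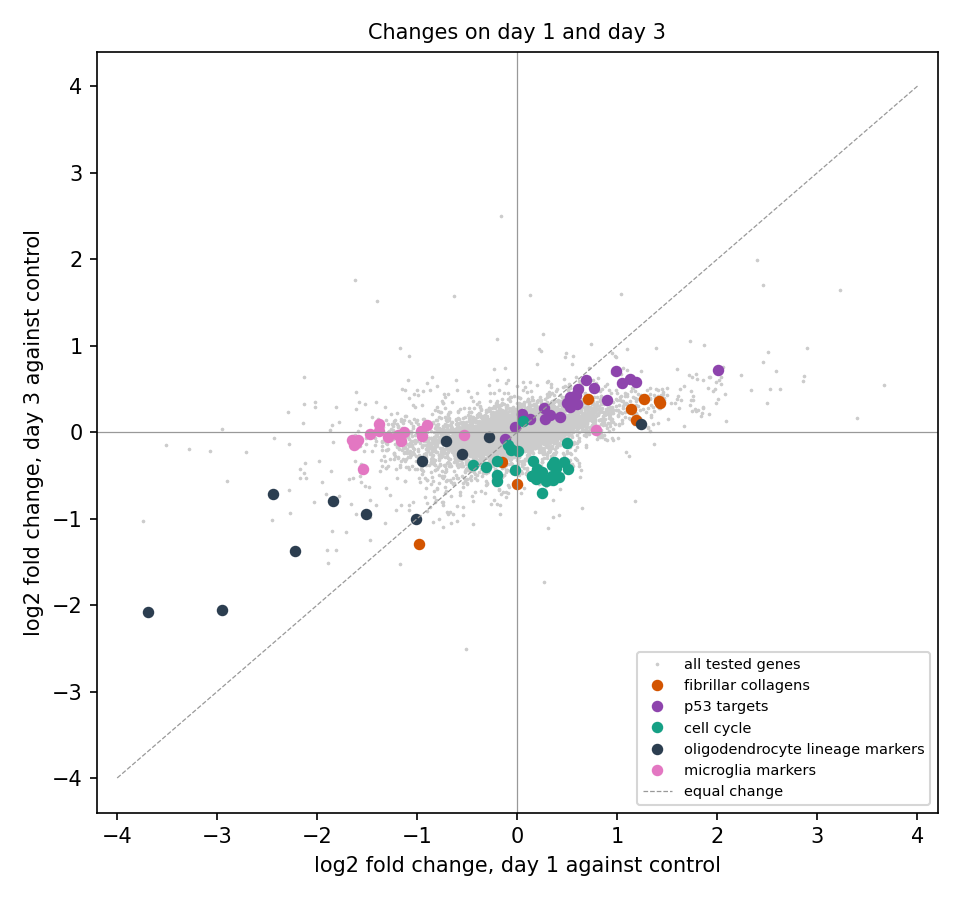
Log2 fold change against control of each of the 12611 tested genes (grey) on day 1 (horizontal axis) and day 3 (vertical axis), with members of 5 lists in colour and a dashed line of equal change. Oligodendrocyte lineage markers had medians of -1.26 on day 1 and -0.76 on day 3, microglia markers -1.29 and -0.04.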

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

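The tests of fibroblast, microglia, oligodendrocyte lineage and neuron markers were chosen after the values had been seen; those of scaling, depth, gene length and other splits were written down before. Groups of 3 libraries were not examined for outlying libraries.

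The effects at the 2 times differed in the direct test of day 3 against day 1 for 7092 genes, or 56.2% of those tested. They differed for 102 of the 105 named genes, but most of these were picked for large changes in the same data. That number was therefore largely set by the choice. Median log2 fold changes of the lists that differed (day 3 against day 1) were -0.74 for fibrillar collagens, -0.42 for collagen processing, -0.19 for other matrix proteins, -0.47 for TGF-beta genes and -0.87 for mural and smooth muscle markers. They were -0.16 for p53 targets, -0.65 for cell cycle genes, -0.23 for the unfolded protein response and -0.28 for cholesterol synthesis. They were 0.31 for A1 reactive genes, 0.43 for homeostatic astrocyte genes, 0.27 for interferon genes, 1.16 for microglia, 0.62 for oligodendrocyte lineage and 0.56 for ependymal markers. None of these list differences held with an estimated correlation (lowest adjusted p = 0.19).

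For 161 genes the call on day 3 was opposite to that on day 1 and the days differed. The named genes among them, with log2 fold changes of day 3 against day 1, were Tgfbr3 (1.62), Ltbp3 (0.37), Tm4sf1 (0.44), Slc7a11 (0.86), Lum (1.21) and Lcn2 (2.32), and Acta2 (-1.32), Tgfb2 (-0.69), Cenpf (-0.96) and Ccnb1 (-0.94). The day 3 call of Tgfb2 did not hold without control replicate 2 (adjusted p = 0.0559). Independent lists of these sizes would give 541 opposite calls.

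The rise of collagen and matrix genes on day 1 was weighed against 3 technical explanations. A larger share of fibroblasts would raise their markers together. On day 1, 8 of 14 rose (median log2 fold change of the list 0.34), but 5 fell, with Dcn from 45.1 to 9.01 FPKM. On day 3, 9 of 14 rose and none fell (median 0.24), while 6 of 10 fibrillar collagens rose and 3 fell (median 0.21). A larger share of fibroblasts therefore stays open for day 3 and was not tested there. For day 1, a larger share alone would not lower 5 markers. A larger share together with lower levels of some markers per cell cannot be excluded in bulk RNA. For scaling, the median log2 fold change of fibrillar collagens was 0.89 in the FPKM as deposited and 0.92 after rescaling. The rescaling factors ran from -0.0358 to 0.02756 on the log2 scale, too small to produce or remove such a rise. This comparison therefore concerns the rescaling step alone. The deposited FPKM are themselves scaled to library totals, and an effect of that scaling was not tested by it. Whether the collagen RNA came from astrocytes or from fibroblasts present in every culture cannot be told apart in bulk RNA, since 9 of the 14 fibroblast markers averaged at least 10 FPKM in control. A response of the treated cells to hydrogen peroxide stays open as the biological explanation, as does the time since the medium change, because the labels give no harvest time for the controls.

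The fall of glial lineage markers on day 1 was weighed next. Fewer microglia or oligodendrocyte lineage cells and lower transcript levels per cell cannot be told apart in bulk RNA, since the 16 of 17 and 11 of 12 markers that fell are the pattern itself. Dilution of every other cell type alike could not be decided. The median log2 fold change of the neuron markers lay 1.39 above that of the microglia markers, more than 2 SDs of the microglia values (1.18). However, only 5 of 16 neuron markers were expressed enough to be tested (3 higher, 2 lower), and cultured astrocytes may express them. All 5 ependymal markers fell (median -0.69). On day 3 the microglia markers had a median log2 fold change of -0.04 (camera adjusted p = 0.334) and 9 of 12 oligodendrocyte lineage markers were lower (-0.76, against -1.26 on day 1). A loss of these cells after hydrogen peroxide stays open and was not tested.

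The larger number of calls on day 1 than on day 3 was weighed against depth and gene length. With every library thinned to 23032594 reads, 7467 genes were called on day 1 and 1516 on day 3. After each library's trend with gene length was removed, 7923 and 1813 were called. Neither therefore accounts for the gap, and the harvest time, which the design names, stays open as the explanation.

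With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real split mixes libraries of both groups, so the difference between the groups enters the spread. Few calls in those splits are therefore built in, whatever the cause of the difference. The real split gave 7839 genes for day 1 against control, where the highest other split gave 0. It gave 1742 for day 3 against control and 7092 for day 3 against day 1, where the highest other split gave 1 in both. In each comparison 1 split of the 10, the real one, reached the real count.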

How the results depend on the processing

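Alternatives with limma-voom on recovered reads, quantile normalization, the filter on CPM and the omission of the 2 libraries richest in Rn45s were chosen after seeing the data. edgeR with other size factors and the DESeq2 alternatives were not run, since the values used here are FPKM. On recovered reads, limma-voom gave 3954 higher and 3916 lower genes on day 1. It gave 1319 higher and 1143 lower on day 3, against 929 and 813 in the main fit, and 1796 shared between the days. At an adjusted p under 0.01, day 3 against control gave 411 higher and 340 lower genes, and 564 genes were shared between the days against 1294. Requiring a change of at least 2-fold left 186 higher and 247 lower on day 1, 4 and 21 on day 3, 184 and 106 between the days, 16 shared, and 1 fibrillar collagen on day 3 and 3 between the days; a stricter threshold gives fewer by construction. With an estimated correlation 0, 1 and 0 lists passed on day 1, on day 3 and between the days, and fry, which asks another question, called 27 on day 1. Leaving out each library in turn gave ranges, for day 3 against control, of 534 to 921 genes higher and 464 to 855 lower, and of 765 to 1358 shared; the lowest came without day 3 replicate 3, day 3 replicate 1 and day 3 replicate 3, and 778 were shared without day 3 replicate 1. Fewer libraries lower power, though leaving out day 3 replicate 2 kept 921 higher and 809 lower and gave 1358 shared. That library differed most from the other day 3 libraries (chi-square per degree of freedom 4.22 and 5.45, against 2.5 between replicates 1 and 3). Leaving it out removes spread as well as a library, so it cannot set lost power apart from other causes. The cause of the drops was not tested. Gfap between the days turned to -0.10 under quantile normalization (the cause was not tested).

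Other counts over all genes, of fibrillar collagens and of lists passing stayed within 1.5 times: day 1 against control gave 3626 to 3922 higher and 3613 to 3904 lower with each library left out. FPKM as deposited shifted calls against control towards lower, with 3319 higher and 4348 lower on day 1 and 661 and 861 on day 3, and gave 3693 and 3187 between the days. Replicate numbers did not pair the libraries (correlations of deviations from -0.08 to 0.11 for equal numbers, 4 of 9 libraries matching their own number best). The replicate block gave 3943 higher and 3951 lower on day 1 and 969 and 838 on day 3. Of 3360 counts of higher or lower list members under alternatives, 3002 stayed within 1.5 times and 358 did not. Of 3520 values of named genes under alternatives, 3314 kept direction and side of the threshold, 203 fell below it, 2 rose above it and 1 reversed. Among the 203, 16 came from the adjusted p under 0.01 and 93 from the 2-fold requirement, which lose calls by construction. Leaving out 1 library ended 60 calls among 15 of the 176 named results.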

Other observations

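The genes below were chosen after their values were seen, and no list of clock genes was tested. Since 62.2% of all genes tested were called on day 1, chosen calls show little about clock genes as a group. Of 5 genes of the circadian clock, Per1 (log2 fold change -0.53, adjusted p = 1.15e-06), Per2 (-0.60), Per3 (-0.64) and Dbp, a clock output gene (-0.71), fell on day 1, while Arntl, which acts in the opposite arm of the clock, rose by 0.72 (adjusted p = 2.01e-07). On day 3 Per1, Per2, Per3 and Arntl did not pass against control (adjusted p = 0.151, 0.479, 0.96 and 0.0599), and Dbp was still lower (-0.14, adjusted p = 0.0192). The labels give no harvest time for the controls, so an effect of hydrogen peroxide and the time since the medium change cannot be told apart here.

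Xist (11.7 to 13.3 FPKM), Ddx3y (7.44 to 9.29 FPKM) and Eif2s3y (11.4 to 13.7 FPKM) were above 0 in all 9 libraries, so each library held RNA of female and male cells.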
